A study of Mus musculus with 7 samples.

How the data were processed

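PAR-CLIP libraries were made from postnatal day 0 CD-1 mouse retinas cultured for 24 h with 0.1 mM 4-thiouridine in medium with 20% horse serum and irradiated at 365 nm with about 300 mJ/cm2, per the labels' protocols. Each library pooled 6 retinas. RNA was trimmed with micrococcal nuclease, complexes of 100 to 150 kDa were cut out, and cDNA of 80 to 150 nt was sequenced. The 7 libraries fell into 2 groups, 5 made with an Argonaute antibody and 2 made with IgG.

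The submitters' processing notes name CASAVA 1.8.2, STAR, bedtools and the mm10 build; other steps and versions are not given in the sources used here. The score of the crosslink table is, per the file headers, the number of samples that contain a crosslink, and it ran from 2 to 5. The miR-216 table carries no header, and its score was tested on the files: each of the 404 deposited entries had a crosslink of the same score within 15 nt of the start of the match. As read from the values, the tables pool the Argonaute libraries, hold no position found in only 1, and pair each match with a crosslink by distance. A position enters the table only where enough RNA was read in at least 2 libraries, so abundant RNAs are favoured and absence from the table does not show absence of binding. The IgG libraries and per-library values were not analysed here, and read depth is unknown.

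The 404 entries described 394 distinct sites; 10 entries repeated a site for another crosslink, and distinct sites were counted. The largest class of intervals was 6 nt long (330 sites), with 41 of 7 nt and 23 of 8 nt. Of 84 intervals with the sequence GAGATT, 57 were preceded by T and so completed the miR-216a 7mer, which shows that the interval alone understates the match. Match types were therefore read again from sequence. Of 304 exonic crosslinks with a deposited motif type starting within 15 nt, 295 (97.0%) were linked to a site in the deposited table.

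Positions were annotated on the same strand with GENCODE release M21 (Ensembl 96, GRCm38, the mm10 assembly), in the order 3′ UTR, coding sequence, 5′ UTR, noncoding exon, intron and intergenic. Sequence was taken from spliced transcripts, since genome sequence was not used here, so sequence tests cover exonic positions only. All 10989 crosslinks with a transcript base fell on T, the base 4-thiouridine replaces, which checks build and strand. The 3062 positions outside exons had no sequence test, and 55 exonic positions had no full window.

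Shares have exact 95% Clopper-Pearson intervals. Site classes were compared with two-sided Fisher's exact tests between the 394 sites and the crosslinks not within 20 nt of a site, with Benjamini-Hochberg adjustment over the classes. Matches of 35 microRNA families were counted in 20 nt on either side of the crosslink and compared with 100 dinucleotide shuffles of each window, with an exact test on the counts and adjustment over the families at 0.05. Families were called neural, broad or of other tissues beforehand. Gene lists with at least 3 crosslinked genes were tested against 100000 random draws of crosslink positions (permutation test, two-sided). Lists were fixed for amacrine, ganglion, photoreceptor, bipolar, horizontal, progenitor and Müller glia genes, other ocular cell types, forkhead factors, the microRNA, Notch, Wnt and TGF-beta and BMP pathways, axon guidance, cell cycle, chromatin regulators, RNA-binding proteins and ribosomal proteins. The comparison of classes by number of libraries was not among those set beforehand. The same holds for the test of recurrence at linked crosslinks and for the sides of family matches. Groups, the main tests, lists, families and the naming rule were otherwise set before the data were examined; the alternatives and closing tests added later are named in the closing section.

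The genes named are Foxn3; up to 10 genes with the most miR-216 sites; the 15 genes whose miR-216 site had the highest score; up to 5 members of each list with a site; and the 10 genes with the most crosslink positions, with ties taken by symbol. This gave 49 genes, of which 1 is not reported here. Of the genes with 2 sites, 16 were tied and not all are named by this rule.

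The family test was tested on simulated data over 10934 windows. All 5 families planted at 2 times the expected number were called (median ratio 1.92), as were all 5 planted at 4 times (median 4.06). Of 25 families that were not planted, 2 were called, miR-103/107 and miR-130, whose 7mers overlap those of planted families. The list test, run on the lists of chromatin regulators and RNA-binding proteins, called 0 of 60 simulated lists with no planted difference at an unadjusted p of 0.05, 41.7% with positions weighted 2 times and 95% with positions weighted 4 times, over 4957 genes.

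Alternatives changed the distance that links sites to crosslinks, the search window, the order of annotation classes, the merging of close positions, the background windows, the match type, the gene-level test and the libraries required. Background windows 100 nt away were taken along the spliced transcript. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.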

Results

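Argonaute-bound RNA was mapped in neonatal mouse retina by PAR-CLIP, in which 4-thiouridine is built into RNA, ultraviolet light at 365 nm links it to the protein that touches it, and the protein is pulled down with its RNA. Retinas of CD-1 mice at postnatal day 0 were cultured for 24 h, and each library was made from 6 pooled retinas. There were 5 libraries made with an antibody to Argonaute, the protein that carries microRNAs, and 2 control libraries made with IgG. The deposited tables pool the Argonaute libraries: 1 lists crosslink positions with the number of libraries that share each, and the other lists matches to miR-216a and miR-216b near those positions. Values of the IgG libraries and of single Argonaute libraries were not analysed here, so no difference was tested against replicate spread, and the read depth behind each position is unknown. Positions, sites and genes are not independent replicates, and the 95% intervals cover counting error only.

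The first question was where Argonaute was crosslinked. The table held 14054 positions in 4957 genes, and 7336 of them (52.2%, exact binomial interval 51.4 to 53.0) lay in 3′ UTRs, the part of an mRNA where most known microRNA sites are found. Coding sequence held 2924 positions (20.8%) and introns held 2520 (17.9%). Noncoding exons held 4.45%, intergenic sequence 3.86% and 5′ UTRs 0.761%. Malat1, a nuclear noncoding RNA, had the most positions, with 146. Rorb, a nuclear receptor needed for rod and horizontal cell development, had 105 positions, of which 63 were intronic and 26 lay in the 3′ UTR. Nlgn1, a postsynaptic adhesion protein, had 85, of which 84 were intronic. The next genes were Map1b with 34, Xist with 33, Ncam1 with 31, Nrxn3 with 29, Auts2 with 27 and Tnrc6a with 26. Neurod1, a proneural transcription factor, had 24 positions, as did Onecut2 and Phip, and 19 of those in Neurod1 lay in its 3′ UTR.

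The share of 3′ UTR positions was higher among positions shared by more Argonaute libraries. It was 47.1% of the 10456 positions in 2 libraries, 62.6% of the 2220 in 3 libraries, 72.5% of the 891 in 4 libraries and 77.2% (73.2 to 80.9) of the 487 in 5 libraries. The intronic share was 21.9% in 2 libraries and 1.44% (0.580 to 2.94) in 5 libraries. Coding sequence went from 21.9% to 13.1%. A 3′ UTR position was found in 3 or more libraries more often than another position, with an odds ratio of 2.28 (2.11 to 2.47; two-sided Fisher's exact test, p = 2.65e-96). Genes with several positions in all 5 libraries included Malat1 with 10, Neurod1 with 4 and Map1b with 3. Ddx3x also had 4, and Casz1, Mybl1, Rnf111 and Fndc3a had 3 each; those of these genes that no naming rule took were chosen after their values were seen.

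**Figure D1:**
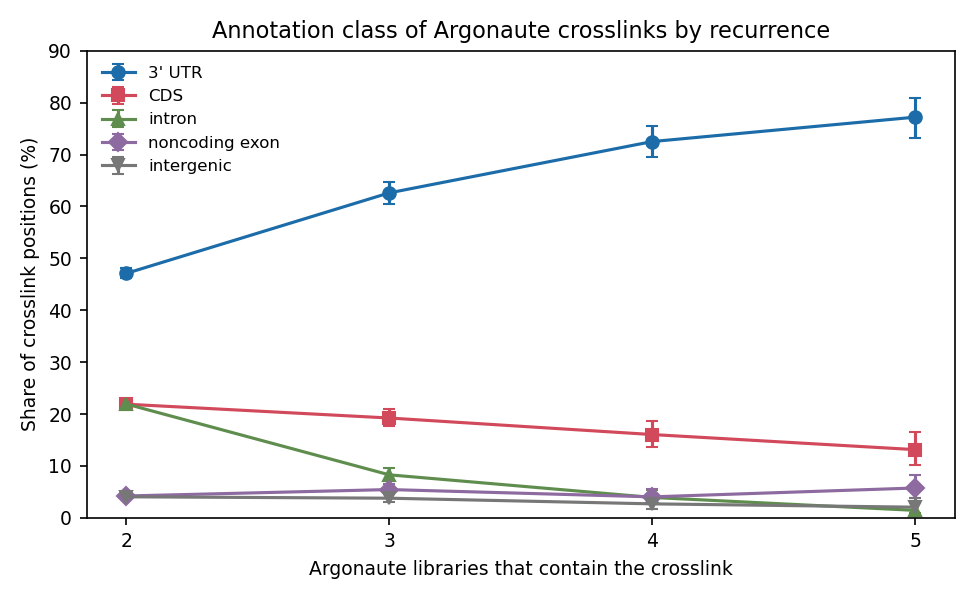
Share of crosslink positions in each annotation class except 5′ UTR (vertical axis, percent) against the number of Argonaute libraries that contain the position (horizontal axis); points are shares of pooled positions and bars are exact 95% binomial intervals. The 3′ UTR share goes from 47.1% in 2 libraries to 77.2% in 5, and the intronic share from 21.9% to 1.44%.

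The series is about miR-216b and Foxn3, a forkhead transcription repressor, in the making of amacrine cells, the inhibitory interneurons of the inner retina. The Foxn3 gene (ENSMUSG00000033713.12, chromosome 12, 99190078 to 99563582, minus strand, mm10) held 6 crosslink positions and 1 miR-216 site. The site lay at 99196033 to 99196038 in the 3′ UTR in exon 6 of 6 of ENSMUST00000046859.11, 232 nt from the start of a 6192 nt UTR. It was named for both miR-216a and miR-216b, its sequence was GAGATT, and its crosslink, at 99196034, was found in 5 of 5 Argonaute libraries. The 41 nt around that crosslink read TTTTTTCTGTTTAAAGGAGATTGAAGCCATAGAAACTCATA. The base before the match was G and the base after it was G, so it was a 6mer and neither a 7mer nor an 8mer of either microRNA. The same 41 nt also held an 8mer match to miR-135-5p, AAGCCAT with A after it, which started 3 nt after the crosslink. Of the 70 matches to miR-135 near crosslinks, 20 began 1 nt after the crosslink and 1, that of Foxn3, began 3 nt after it. The other Foxn3 positions in the 3′ UTR, at 99191601, 99192870, 99196013 and 99196015, were each found in 2 libraries, and an intronic position at 99257463 was found in 3.

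**Figure D2:**
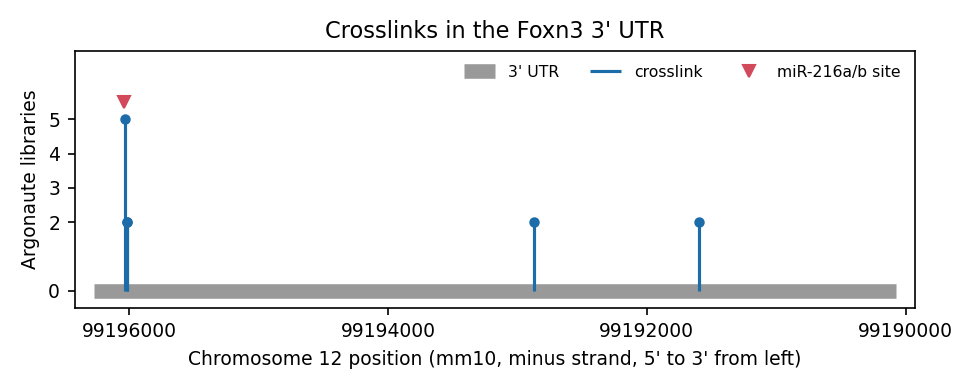
Crosslink positions along the Foxn3 3′ UTR (horizontal axis, chromosome 12 position in mm10, drawn 5′ to 3′), with the number of Argonaute libraries that contain each (vertical axis); the grey bar is the UTR and the triangle is the miR-216a/b site. The position inside the site was found in 5 libraries and the other 4 UTR positions in 2 each.

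Across the transcriptome, the miR-216 table held 394 distinct sites in 339 genes, linked to 399 crosslink positions, or 2.84% (2.57 to 3.13) of the total. Of these genes, 318 had 1 site, 16 had 2, 3 had 3 and 2 had more. Malat1 had 5 sites in its noncoding exon and Nlgn1 had 4, all intronic. Cdh2, encoding N-cadherin, had 3 intronic sites. Dyrk2, a protein kinase, had 3 sites in its 3′ UTR. Rorb had 1 site in coding sequence and 2 in introns. Among the genes with 2 sites, Ccnj, a cyclin, had both as 8mers in its 3′ UTR, at 40848350 to 40848355 and 40848385 to 40848391 on chromosome 19, in 2 and 3 libraries. B230219D22Rik and Eaf1 had both sites in the 3′ UTR, Asxl1 had both in coding sequence, and Celf2 had both in introns. All 394 sites had a crosslink within 20 nt on the same strand, and the deposited intervals of 104 overlapped the crosslinked base.

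The sites with the most recurrent crosslinks were in 14 genes whose linked position was found in all 5 libraries. Besides Foxn3, the sites of Mybl1, Arfgef1, Synpr, Slc16a1, Megf9, Rnf6, Eif4g2 and Atxn1l lay in 3′ UTRs, those of Eif5, Strbp and Asxl1 in coding sequence and that of E130308A19Rik in an intron. Strbp had an 8mer match to miR-216a at 37603089 to 37603094 on chromosome 2, in exon 11 of 17. Rnf6 and Eif5 had 7mer-m8 matches to miR-216b. Of the 19 sites with a linked position in 4 libraries, the naming rule took that of Atg4a, which is intronic, by symbol alone. Overall 24.6% (20.4 to 29.1) of linked crosslinks and 25.6% (24.9 to 26.4) of other crosslinks were in 3 or more libraries, and this difference did not pass the test (odds ratio 0.945, 0.750 to 1.19; two-sided Fisher's exact test, p = 0.684).

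The comparison of site classes asked whether miR-216 sites lay in 3′ UTRs as often as other Argonaute positions did. Over all sites the 3′ UTR share was lower, at 45.9% (181 of 394, 40.9 to 51.0) against 52.3% (7136 of 13635, 51.5 to 53.2), with an odds ratio of 0.774 (0.633 to 0.946; two-sided Fisher's exact test, p = 0.0140, q = 0.0420 over 6 classes). Intergenic sequence held 6.60% of sites against 3.79% of other positions (odds ratio 1.79, 1.19 to 2.69, q = 0.0420). A single intergenic stretch of chromosome Y, from 90735062 to 90738738, held 6 of the 26 intergenic sites and 5 of the 10 intergenic sites in 3 or more libraries. Without chromosome Y, the intergenic shares were 5.18% (20 of 386) and 3.74% (odds ratio 1.41, 0.889 to 2.23, q = 0.411), and the 3′ UTR odds ratio was 0.802 (0.655 to 0.982; Fisher's exact test, p = 0.0341, q = 0.205), so neither passed the adjusted test. With close positions merged neither passed it (q = 0.0920 for both). Among sites in 3 or more libraries, the odds ratios were 0.607 (q = 0.0507) for 3′ UTRs and 3.52 (q = 0.00791) for intergenic sequence, and without chromosome Y 0.719 and 1.85 (q = 0.412 for both). Shares in coding sequence (22.8% and 20.7%), introns (19.3% and 18.0%), noncoding exons (4.82% and 4.40%) and 5′ UTRs (0.508% and 0.770%) did not pass the test.

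Sequence could be read for 289 of the 292 sites in annotated exons, to ask how well each paired with the seed, the part of a microRNA that sets its targets. A full 7mer-m8 match to miR-216a or miR-216b was present in 91 sites (31.5%, 26.2 to 37.2), of which 59 matched miR-216a and 32 matched miR-216b. An 8mer was present in 19 (6.57%, 4.00 to 9.67). The largest class was the offset 6mer, TGAGAT or AGAGAT, as the best match of 156 sites (54.0%, 48.0 to 59.8). The 6mer GAGATT was present in 115 sites (39.8%), and a bulged match was the best of 18 sites. With only 10 nt searched on either side of the 302 linked exonic crosslinks, the 7mer-m8 share was 17.5% and the GAGATT share 22.2%. Deposited intervals with a gap of 1 to 8 nt from the crosslink were downstream of it in 93 entries and upstream in 86 (52.0%, 44.4 to 59.5; two-sided exact binomial test, p = 0.654), and the sign of this difference turned under each of the other windows tried. Of the 93, 26 started 1 nt after the crosslink. Some of these, such as the Malat1 site at 5800380 to 5800385, had the crosslinked T as first base of a full miR-216a 7mer, so the crosslink lay inside that 7mer. Without crosslinks 1 nt from the match, the counts were 67 downstream and 81 upstream.

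Gene lists for retinal cell types and pathways were compared with random draws of as many crosslink positions. None of the 16 lists tested passed the permutation test after Benjamini-Hochberg adjustment, and 0 had an unadjusted p under 0.05. A Fisher's exact test over genes also gave 0 adjusted calls and 1 unadjusted, for photoreceptor genes (p = 0.0137, q = 0.219). Of the amacrine cell genes, 13 had a crosslink and 1, Neurod1, had a miR-216 site, against 2.38 expected (permutation test, p = 0.526). Other amacrine genes with crosslinks and no site included Neurod4 with 14 positions, Meis2 with 12, Tcf4 with 10 and Pax6 with 7. Photoreceptor genes had 3 of 8 with a site, Mef2d, Neurod1 and Rorb. Horizontal cell genes had 1 of 5, Onecut1, while ganglion cell genes had 0 of 14 and bipolar cell genes 0 of 6. Progenitor and Müller glia genes had 2 of 17, among them the Notch effector Hes1, whose offset 6mer had a crosslink in 4 libraries. Of markers of other ocular cell types, such as pigment epithelium, microglia and vessels, only Kdr and Pdgfra had crosslinks, neither had a site, and the list was too small to test.

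Among pathways, microRNA pathway genes had 3 of 18 with a site, namely Tnrc6a, which encodes a partner of Argonaute, and the deadenylase subunits Cnot6 and Cnot6l. Each site had its crosslink in 2 libraries. Tnrc6a had an offset 6mer and Cnot6l a bulged match, both in 3′ UTRs. The Cnot6 site was intronic, while its crosslink lay in exon 3 of 12. The spliced sequence around that crosslink lacked the site and held an 8mer match to miR-125 starting 3 nt after it. RNA-binding proteins had 4 of 36, Celf2, Elavl2, Mbnl2 and Qk. Chromatin regulators had 3 of 34, Kmt2c, Kmt2d and Suz12. Axon guidance genes had 3 of 29, Epha5, Plxnb2 and Sema4b. The TGF-beta and BMP pathway had 2 of 17, Skil and Smad5. Notch had 1 of 17, Hes1. Wnt had 1 of 13, Tle4. Cell cycle genes had 1 of 21, Ccne2. Forkhead factors had 1 of 5, Foxn3. Ribosomal proteins had 0 of 11. In simulated data for the 2 lists with the most crosslinked genes, chromatin regulators and RNA-binding proteins, a list whose positions were drawn with 2 times the weight passed the unadjusted test in 41.7% of 60 runs and with 4 times in 95%. Power for the other lists was not simulated.

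To ask which microRNAs guided Argonaute in these retinas, 7mer-m8 matches of 35 microRNA families were counted in 41 nt around 10934 exonic crosslinks and compared with shuffled windows of the same dinucleotide content. Matches were more frequent for 23 families and less frequent for 3 (exact test, q under 0.05). The highest ratios were those of let-7 (10.2, 8.85 to 11.7), miR-124 (9.94, 8.99 to 11), miR-17/20/93 (8.23, 7.42 to 9.12), miR-9 (6.63, 5.81 to 7.54) and miR-19 (6.21, 5.57 to 6.91). Of the 15 families of neural or retinal tissue, 11 were enriched, among them miR-125 (5.09), miR-181 (4.72), miR-96 (3.63), miR-182 (3.60), miR-204 (2.84) and miR-183 (2.22), the last being part of a sensory-organ cluster with miR-96 and miR-182. Of the 11 broadly expressed families, 10 were enriched and miR-29 (0.668) was depleted. Of 7 families of other tissues, miR-133 (1.64) and the miR-1 family (1.58) were enriched, while miR-122 (0.524) and miR-223 (0.513) were depleted. The calls of miR-133 and the miR-1 family depended on the setting. Neither passed the test in 3 or more libraries (0.904 and 1.32) or at 3′ UTR crosslinks alone (1.51 and 1.22). Against background windows along the spliced transcript, neither passed it (1.57 and 1.28). Both passed it with 8mer matches (2.99 and 2.88) and at coding sequence crosslinks alone (2.04 and 2.29). Some families share part of their match, such as miR-19 with miR-130, so their counts are not separate.

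Matches to miR-216a (64 against 54.9 expected, ratio 1.17, 0.897 to 1.49, q = 0.25) and to miR-216b (48 against 40.8, ratio 1.18, 0.866 to 1.56, q = 0.295) did not pass the test. Among 16135 7mers ranked by ratio, they were at 4358 and 4233. The median ratio of all 7mers in these windows was 0.902. The intervals leave room for an excess of up to 1.49 times for miR-216a and 1.56 times for miR-216b. miR-216a passed the test with 10 nt on either side (1.71, 1.19 to 2.37, q = 0.00519) and against windows 100 nt away (2.24, 1.5 to 3.33, q = 6.94e-05). miR-216b passed it under none of the settings tried.

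**Figure D3:**
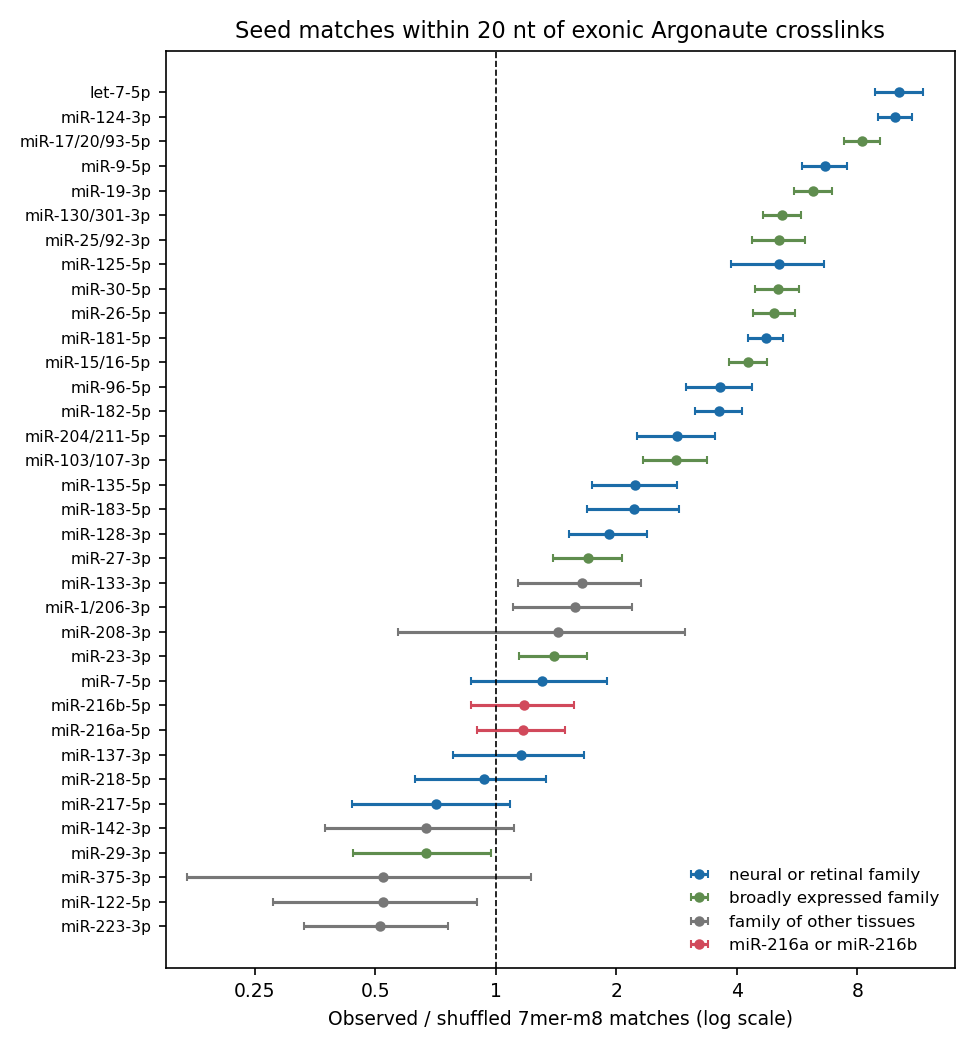
Ratio of observed to shuffled 7mer-m8 matches (horizontal axis, log scale) within 20 nt of exonic Argonaute crosslinks for 35 microRNA families (vertical axis); bars are 95% intervals and colours mark the kind of family. let-7 and miR-124 lie near a ratio of 10, and miR-216a and miR-216b lie at 1.17 and 1.18 with intervals that include 1.

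Matches of most enriched families lay after the crosslink. Of those clear of the crosslinked base, 81.8% (80.5 to 83.1) started after it, 2927 against 650 before it, and the most frequent start for let-7, miR-124, miR-17/20/93 and miR-9 was 1 nt after the crosslinked T. An exact binomial test was passed for this side by 19 of the 23 enriched families and for the opposite side by miR-133 (9 after, 25 before, q = 0.0167), while miR-103, miR-128 and the miR-1 family passed for neither. The 112 matches of miR-216a and miR-216b started after the crosslink in 33 cases and ended before it in 41 (44.6% after, 33.0 to 56.6). The other 38 had the crosslink inside, among them 31 of the 64 of miR-216a. Of these, 18 began at the crosslinked T itself, which was also the most frequent start for miR-19, with 123 of 356 matches. At the 13 exonic crosslinks in 5 libraries that were linked to a miR-216 site, 9 had a 7mer of an enriched family starting from 1 nt before to 3 nt after the crosslink (69.2%, 38.6 to 90.9), beside 239 of 453 (52.8%, 48.0 to 57.4) at other crosslinks in 5 libraries. With starts from 0 to 2 nt after the crosslink, the count was 7 of 13 beside 225 of 453. The shares at linked and other positions, for the wider range of starts, were 16.1% and 20.8% in 2 libraries, 24.5% and 37.3% in 3, and 25% and 47.1% in 4. None of these differences passed a two-sided Fisher's exact test after adjustment over the 4 classes, with either range (lowest q = 0.169 for the wider and 0.0846 for the narrower). The 9 sites in 5 libraries with such a match had miR-19 in Arfgef1, miR-124 in Asxl1 and Slc16a1, miR-17/20/93 in Eif4g2, miR-182 in Eif5, miR-135 in Foxn3, miR-15/16 in Mybl1, miR-30 in Rnf6 and miR-181 in Synpr. Atxn1l, Megf9 and Strbp were among those with none.

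**Figure D4:**
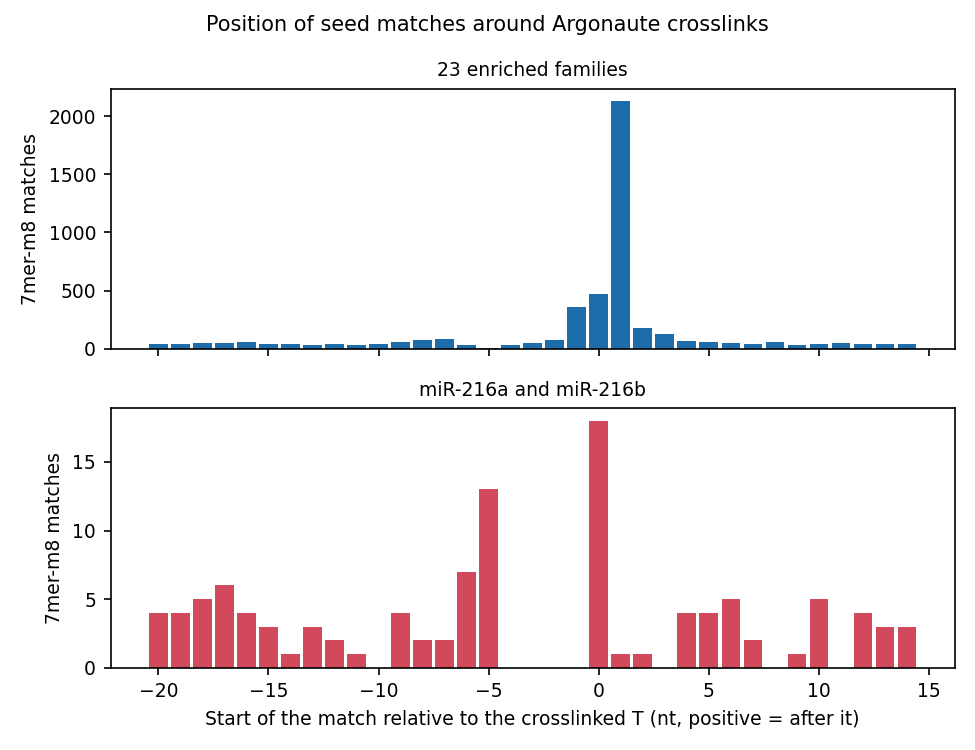
Number of 7mer-m8 matches (vertical axis) by the start of the match relative to the crosslinked T (horizontal axis, nt, positive after it), for the 23 enriched families (top) and for miR-216a and miR-216b (bottom). The enriched families peak 1 nt after the crosslink, and the miR-216 matches have 18 at the crosslinked T.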

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

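Alternatives that require 3 or more libraries, leave out Malat1, chromosome Y, introns or overlapping windows, keep 3′ UTR crosslinks only in the family test, leave out crosslinks 1 nt from the match, or vary the classes by number of libraries were chosen after the data were seen. No paired analysis was possible because the deposited tables are pooled and carry no values per library, and for the same reason no library could be left out in turn. A limit at the median score removed nothing, since the median is 2, the lowest score, and its 8 values say nothing about stability. Of the other 48 values, 30 counted as unchanged. Tests counted so by direction and side of the threshold, and overlap and seed match shares by lying inside the main interval. The overlap within 50 nt and with strand ignored could not differ from 394, since every site had a crosslink within 20 nt on its strand. The lower 3′ UTR share of miR-216 sites stayed lower throughout. It lost its adjusted call among sites in 3 or more libraries (odds ratio 0.607, q = 0.0507), with close positions merged (0.80, q = 0.0920), without chromosome Y (0.802, q = 0.205) and in 3 or more libraries without chromosome Y (0.719, q = 0.412). The higher intergenic share lost its call when merged (1.73), without chromosome Y (1.41) and in 3 or more libraries without chromosome Y (1.85). Leaving out chromosome Y kept 386 of the 394 sites, and 6 neighbouring intergenic sites were among those removed. The 3′ UTR odds ratio then moved little, from 0.774 to 0.802 (Fisher's exact test, p = 0.0140 and 0.0341). Its q also depends on the other classes, and the intergenic p of the same test went from 0.00760 to 0.137. The causes of the other losses were not tested. The rise of the 3′ UTR share with recurrence kept its call, with odds ratios from 1.73 to 2.36. Under these alternatives the number of enriched families was 21 to 23, and no gene list was called. The family test at coding sequence crosslinks alone, given above for miR-133 and the miR-1 family, was not among them.

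Sites whose deposited interval overlapped the crosslinked base numbered 104 in place of 394 within 20 nt, by construction of the distance. The 7mer-m8 share was 17.5% and the GAGATT share 22.2% with 10 nt searched, which sees fewer of the matches, and 41% and 48.2% at sites in 3 or more libraries; the cause of that rise was not tested. The downstream share of matches was 45.3% without crosslinks 1 nt from the match, 43.3% with 10 nt and 49.1% with 50 nt, against 52.0% in the report, and none of these passed the test. miR-216a was enriched with 10 nt (1.71) and against windows 100 nt away (2.24); the cause of the second was not tested. The 8mer of miR-216b had a ratio of 0.900 (0.387 to 1.78) from 8 matches. Read depth per position is unknown, and counts this low limit what can be said of miR-216b.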

Other observations

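The tests of T bases, of guidance by miR-216 and of seeds of other families were chosen after the result was seen, as were the division of families by number of libraries and the genes in the next paragraph that the naming rule did not take.

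Of 2520 intronic positions in 1326 genes, Nlgn1 held 84, Rorb 63, Nrxn3 26, Auts2 25, Grip1 21 and Ncam1 17. Argonaute crosslinks lay in RNAs of the microRNA silencing machinery: 18 of 22 listed genes held 147 positions, with 26 in Tnrc6a, 23 in Tnrc6b and 20 in Dicer1. The last 2 genes had 2 positions each in all 5 libraries. Such positions were not particular to this list. Of 40 RNA-binding protein genes, 36 held 186 positions, and 34 of 45 chromatin regulators held 172. Photoreceptor genes had 8 of 20 with 171 positions, 105 of them in Rorb, and 13 of 27 amacrine cell genes held 98. Among ganglion cell genes, Sox4 had 12 positions and Sox11 had 10, and among photoreceptor genes Prdm1 had 22 and Casz1 had 8, all without a miR-216 site.

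The pooled ratio of neural families was 3.47 (3.28 to 3.67) at crosslinks in 2 libraries and 5.59 (4.67 to 6.65) at those in 5, with intervals that do not overlap, and that of broad families went from 3.56 to 6.31. The pooled ratio of miR-216a and miR-216b was 1.08 (0.845 to 1.35), 1.45 (0.936 to 2.15), 1.37 (0.591 to 2.73) and 1.29 (0.415 to 3.03) in 2, 3, 4 and 5 libraries. In 3 or more libraries the ratio was 1.33 (0.832 to 2.02) for miR-216a and 1.54 (0.874 to 2.51) for miR-216b, and neither passed the test. The ratio of families of other tissues was 0.959, 0.650, 0.457 and 1.22 in 2, 3, 4 and 5 libraries, the last from 7 matches. The 7mers of highest ratio were TACCTCA (10.2) and CTACCTC (10.2), which overlap and both pair with let-7.

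Matches to miR-216 were about as frequent near crosslinks as in shuffled windows: the ratio was 0.920 (0.818 to 1.03) for all deposited motif types, 0.962 (0.765 to 1.19) at crosslinks in 3 or more libraries and 1.17 (0.963 to 1.41) for full 7mers, so base composition may account for most of the exonic sites. The median ratio of all 7mers in the 41 nt windows was 0.902, so a ratio of 1 was not the typical value of a 7mer there. Full 7mers of miR-216 clear of the crosslinked base started after the crosslink less often than matches of the enriched families (odds ratio 0.179, 0.112 to 0.285). This cannot decide guidance, because the 38 matches with the crosslink inside were left out. A ratio near 1 also lowers this share beside families of high ratio. Some enriched families lacked that place too, such as miR-103 (16 after, 17 before) and the miR-1 family (11 after, 12 before). Within 10 nt the ratio of TGAGATT was 1.66 in a separate run of 20 shuffles, inside the central 95% (0.307 to 3.01) of 79 other 7mers with T at the same positions, but their median was 0.833 and it ranked 10, so whether the crosslinked T by itself gives the excess of miR-216a there stays open; whether its first T was preferred, as guidance at those matches would need, is open too (odds ratio 1.19, 0.578 to 2.46). Seeds of other families are a candidate explanation for sites such as those of Mybl1 and Slc16a1: they began 0 to 2 nt after 19.4% of crosslinks whose miR-216 match left room and 24.4% of others (odds ratio 0.744, 0.498 to 1.11), while the share over the whole window (26.8% against 35.6%, odds ratio 0.660) cannot decide, because the miR-216 match itself takes room. Guidance was tested only through the place of the matches, since retinas without miR-216 are not part of the design and IgG values were not analysed here, and single sites such as the 8mers of Ccnj stay open. The crosslink linked to the Ccnj site at 40848385 also had an 8mer match to miR-27, starting 3 nt after that crosslink.

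Among 296 exonic pairs of a miR-216 match and its crosslink, the crosslink lay inside the match in 71 (24.0%). Moving each crosslink to a random T within the same distance gave 23.8% (19.3 to 28.7), so the positions of T in the motif may account for this share. No biological explanation was tested.

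The share of 3′ UTR positions rose with the number of libraries, and the abundance of the bound RNA is a technical explanation, since abundant RNAs are seen in more libraries. Within 877 genes with positions in both classes, 3′ UTR positions were still found in 3 or more libraries more often than coding positions of the same genes (Mantel-Haenszel odds ratio 1.71, 1.46 to 2.00), which argues against abundance of the gene as the whole cause. Transcripts of a gene that differ in their 3′ UTR, and read depth at each position, stay open as untested. Longer occupancy of Argonaute on 3′ UTRs is a hypothesis consistent with the 1.71 found within genes, and no test here separates it from these.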
